A study of Mus musculus with 16 samples.

How the data were processed

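Dendritic cells of the cDC1 type were sorted on day 6 after tumour injection from inguinal lymph nodes that had been digested with collagenase B and DNase I, per the labels' protocols. RNA from 16 samples was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 sample per array. The groups were Het draining, Het non-draining, KO draining and KO non-draining, with 4 arrays each, and were taken from the sample labels together with the replicate numbers 1 to 4. The deposited table holds intensity values on a linear scale, between 3.327 and 16300.089, for 35556 probe sets, and the arrays had been normalized with RMA per the submitters' processing notes. The RMA software and its version are not given in the sources used here. RMA shares one intensity distribution over the arrays and pulls dim probe sets toward a common floor, so differences of dim genes are understated and a shift of all genes together would be removed.

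The values were tested as log2(intensity + 1), because the table turned out to be linear. Of the probe sets, 21789 carried 1 gene symbol in the platform annotation, 1621 several and 12146 none. The gene ID matched the mouse gene table (GRCm38.p6) for 21698 of them (99.6% of those with 1 symbol), and 0 symbols changed. A gene was represented by its brightest probe set over all arrays, which gave 19938 genes, 999 of them with more than 1 probe set. The 13767 unnamed or shared probe sets were tested apart and gave 0 calls in limma in each comparison, with between 359 and 708 at an unadjusted p under 0.05. No column of the table was left without a sample, and no value was missing. Some members of the fixed lists were not analysed here.

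Differences were tested two-sided with limma 3.58.1 in R 4.3.3, in a single fit of the 4 groups over 16 arrays with 12 residual degrees of freedom and an estimated prior of 4.35. The 7 comparisons were KO against Het in each node, draining against non-draining in each genotype, the interaction, and the mean of the genotype difference over both nodes and of the node difference over both genotypes. P-values were adjusted with the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Errors given after ± are standard errors from limma for differences and SDs for group means. The median standard error was 0.12 for the 4 simple comparisons, 0.18 for the interaction and 0.09 for the comparisons of means. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

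The groups, the comparisons, the main test, the rule for named genes, 30 gene lists and most alternatives were chosen before the data were examined. The rule named Wdfy4, the genes past the threshold with groups that did not overlap, and, where fewer than 5 genes passed in a direction, those of smallest p up to 5, which then failed the test. It added up to 4 members of smallest p per list and any member of a list of 8 or fewer genes, and it left out predicted genes, small RNA genes and receptor segments. Gm4951, a predicted gene and the gene of smallest p in KO against Het cells of the draining node and in the interaction, falls outside this rule and was named after its values were seen. Where a list is described, its members higher or lower are counted by the sign of the difference.

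The lists covered cDC1 identity, cross-presentation and vesicle traffic, MHC class I processing, MHC class II presentation, the BEACH domain family, neighbours of Wdfy4, type I interferon response, interferon gamma response, dendritic cell maturation, cytokines and chemokines for T cells, cell cycle, cholesterol synthesis, liver X receptor targets, glycolysis, oxidative phosphorylation, lysosome, endoplasmic reticulum stress, and immediate early and tissue digestion genes. Markers of other cells covered T cells, NK and cytotoxic cells, B cells, plasma cells, macrophages and monocytes, plasmacytoid dendritic cells, cDC2, skin migratory dendritic cells and Langerhans cells, neutrophils, lymph node stromal cells, erythroid cells and sex-linked genes. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists within a comparison, and again with an estimated correlation. Median, mean and test had the same sign in all 42 results where a list passed with the preset correlation. Of the other 168 results of a list in a comparison, 26 differed in sign between them, with medians of at most 0.06 in size and adjusted p values of at least 0.405.

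An exact two-sided permutation of the list means per array was added after seeing the data. Its smallest p for 4 against 4 arrays is 0.0286, and for the comparisons of means it permuted genotype within nodes or node within genotypes. For the interaction it permuted node within each genotype. This also undoes any node difference that both genotypes share, so there it is not an exact test of the interaction alone. For these and the interaction it was repeated, also after seeing the data, with the draining and non-draining array of a genotype and number kept together, since same-numbered Het arrays deviated together. The alternatives chosen before were the replicate number as a fixed block, a random block of genotype and number, a trended and robust prior, a fit of the compared groups alone, dim genes left out, the mean of a gene's probe sets, every probe set on its own, repeated quantile normalization, median centring, array weights, a fold threshold and leaving out each array in turn. Those added after seeing the data were arrays numbered 1 and 2 against 3 and 4 as a block, each of these sets alone, and the replicate block within the compared groups.

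The replicate numbers, which come from the labels, were checked for pairing by correlating the deviations of same-numbered arrays from their group means. For Het draining and Het non-draining arrays all 4 correlations lay between 0.199 and 0.314, so these arrays were taken as paired and blocked values are given where they change a call, although only 2 of the 4 draining arrays correlated best with their own number. The model was tested on simulated data with 200 of 19938 genes changed, 50 per size. The simulated noise was independent between genes, so the shares called hold for such data only. For the interaction 76% of genes changed by 1 on the log2 scale were called and 22% of those changed by 0.5, for the genotype difference over both nodes 100% and 84%, and for the node difference over both genotypes 98% and 70%. The number of arrays limits the precision.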

Results

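Gene expression was measured in type 1 conventional dendritic cells (cDC1), the dendritic cell subset that takes up dead cells and presents their antigens on MHC class I to CD8 T cells. The cells came from C57BL/6 mice that carried either 1 intact copy of Wdfy4 (Het) or none (KO). WDFY4 is a large BEACH-domain protein that cDC1 need to cross-present cell-associated antigen. Mice received tumours of a type that is later rejected in the flank, and 6 days later cDC1 were sorted from inguinal lymph nodes on the side that drains the tumour or on the side that does not. Each of the 4 groups had 4 arrays, 16 in all, and the arrays carry the numbers 1 to 4 within each group. The labels do not say that the arrays of a group came from separate mice, so the p-values measure the spread between these samples, which may be partly technical. Arrays have no read depth, and their number limits the precision; the median intensity per array lay between 38.6 and 40.8.

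The targeted gene was read first. The brightest probe set for Wdfy4 (10418848, mouse chromosome 14) gave an intensity of 2252 ± 411 in KO and 2957 ± 433 in Het cells of the draining node (SD, n = 4 each), a log2 difference of -0.40 ± 0.18 (SE) with an exact two-sided permutation p of 0.0857. In the non-draining node it gave 2375 ± 557 in KO and 2804 ± 549 in Het cells, a log2 difference of -0.25 ± 0.18 with an exact permutation p of 0.229. Over both nodes the log2 difference was -0.32, with an exact permutation p of 0.0314 when genotype was permuted within nodes, 0.143 when the arrays of a genotype and number were kept together, and an adjusted p of 1.00 among all genes in limma. The draining difference was -0.42 within arrays 1 and 2 and -0.38 within arrays 3 and 4, and the non-draining one -0.26 and -0.23. Single arrays moved the non-draining difference, which was -0.16 without Het non-draining 1, -0.15 without KO non-draining 3 and -0.39 without KO non-draining 2. With these 2 sets of arrays as a block, a setting chosen after the results were seen, the unadjusted p in limma was 0.00233 in the draining and 0.0404 in the non-draining node. With the replicate number as a block it was 0.00141 and 0.0284, and with a random block of genotype and number 0.0286 and 0.158, and none of these passed over all genes (smallest adjusted p = 0.792). A dimmer probe set (10418868) gave -0.33 in the draining and -0.19 in the non-draining node, with exact permutation p values of 0.371 and 0.60. The labels do not give the deleted part of the gene, a probe set outside it checks nothing, and the Het cells keep an intact copy, so these levels do not check the genotype labels. Lrrc18, a gene that lies within Wdfy4 in the GRCm38.p6 annotation, differed by -0.28 ± 0.15 between KO and Het cells of the non-draining node (adjusted p of 1.00 in limma). The 11 genes chosen as neighbours of Wdfy4 on chromosome 14 had median log2 differences between -0.03 and 0.07 over the 7 comparisons. The list passed in none of them in limma camera (smallest adjusted p = 0.10).

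**Figure D1:**
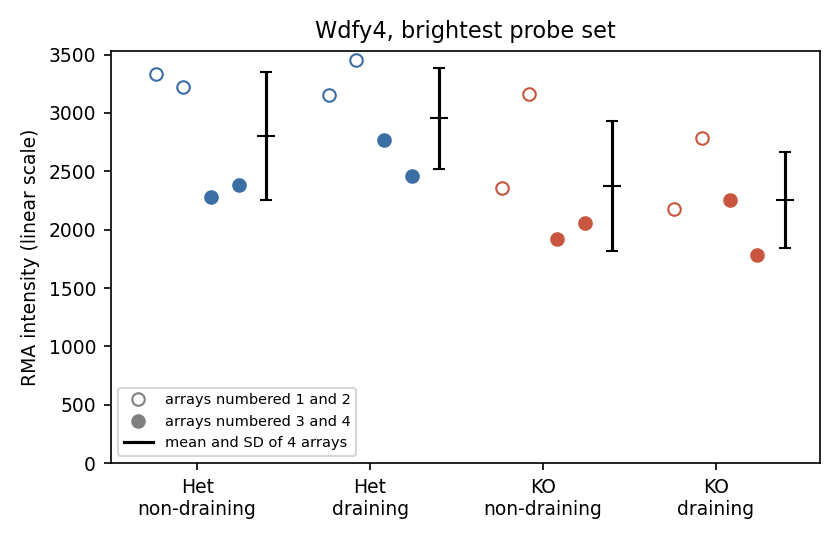
Intensity of the brightest Wdfy4 probe set on the linear scale (vertical axis) for each array of the 4 groups (horizontal axis), with arrays numbered 1 and 2 as open points, arrays numbered 3 and 4 as filled points, and the mean and SD of 4 arrays as bars. KO means of 2252 and 2375 stood below Het means of 2957 and 2804, and the points of KO and Het overlapped. Each KO array lay below the Het array of the same node and number, although the numbers were not taken to pair KO with Het arrays.

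No gene passed an adjusted p of 0.05 in limma in any of the 7 comparisons among 19938 genes. At an unadjusted p under 0.05 there were 675 genes for KO against Het in the draining node, 494 in the non-draining node, 655 for draining against non-draining in Het cells and 421 in KO cells. There were 463 for the interaction, 696 for KO against Het over both nodes and 610 for draining against non-draining over both genotypes. A share of 0.05 of all genes is about 997, but this is not the chance level of these arrays. Other splits of the same arrays, made after the results were seen, gave medians of 1125.5, 522.5, 681 and 749 genes in the 4 simple comparisons, in the order above. Counts under 997 are therefore not a result about the groups. In data simulated on these genes with 4 arrays per group, 90% of genes changed by 1 on the log2 scale were called in the KO against Het comparison of the draining node and 42% of those changed by 0.5. In the non-draining node these shares were 90% and 32%, and for draining against non-draining they were 88% and 40% in Het cells and 88% and 46% in KO cells. The genes named for each comparison are therefore those of smallest p and, except where a test adjusted over a list is given, none of them passed.

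In the draining node, where tumour antigen arrives, the lists of smallest p between KO and Het cells in camera with the preset correlation were immediate early and cell cycle genes. Immediate early genes, which signalling and tissue digestion both induce quickly, were higher in KO cells for 17 of 18 measured members, with a median log2 difference of 0.32. Among them were the AP-1 genes Jun (0.43 ± 0.14, SE) and Junb (0.32 ± 0.12), the cochaperone gene Dnajb1 (0.45 ± 0.17) and the transcription factor gene Klf2 (0.31 ± 0.13). Cell cycle genes were lower in KO cells for 26 of 30 members, with a median of -0.20, and included the mitotic kinase gene Plk1 (-0.88 ± 0.21), the topoisomerase gene Top2a (-0.45 ± 0.15), the replicative helicase gene Mcm7 (-0.39 ± 0.14) and Cdk1 (-0.38 ± 0.15). In camera with a preset correlation both lists passed, with adjusted p values of 3.46e-11 and 1.07e-07, but each had adjusted p = 0.454 with an estimated correlation, and the exact permutation p of the list means was 0.0857 and 0.171. No member of the immediate early list passed over all genes or adjusted over the list alone, while 1 cell cycle member, Plk1, passed adjusted over the list alone and none over all genes. The immediate early median was 0.20 within arrays numbered 1 and 2 and 0.40 within arrays numbered 3 and 4, while the cell cycle median was -0.34 and -0.04, and the latter did not pass in arrays 3 and 4. Without Het draining 4 the immediate early median was 0.21 and the cell cycle median -0.32.

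In the same comparison 3 further lists passed with the preset correlation only. T cell markers were higher in KO arrays for 12 of 13 members, with a median of 0.27 and examples in Cd28 (0.48 ± 0.28) and Cd4 (0.26 ± 0.14). The T cell list had adjusted p = 0.659 with an estimated correlation. Interferon gamma response genes had a median of -0.14, with 10 of 13 members lower, led by the immunity-related GTPase genes Iigp1 (-0.86 ± 0.27) and Irgm1 (-0.25 ± 0.13). The interferon gamma list had adjusted p = 0.454 with an estimated correlation. Cholesterol synthesis genes had a median of -0.17, with 14 of 16 lower, among them Cyp51 (-0.29 ± 0.11) and Msmo1 (-0.47 ± 0.21), while Insig1, which restrains the pathway, stood at 0.36 ± 0.12. The cholesterol list had adjusted p = 0.659 with an estimated correlation. No member of these lists passed over all genes or adjusted over the list alone. Within arrays 1 and 2 and within arrays 3 and 4, the medians were 0.14 and 0.22 for T cell markers, -0.12 and -0.11 for interferon gamma genes and -0.28 and 0.01 for cholesterol genes. The T cell call ended without Het draining 1 (0.14), KO draining 3 (0.13) or KO draining 4 (0.21), and its median was 0.40 without Het draining 3. The interferon gamma call ended without Het draining 3 (-0.09), Het draining 4 (-0.19), KO draining 2 (-0.10) or KO draining 3 (-0.12). The cholesterol call ended without Het draining 2 (-0.24), Het draining 3 (-0.12) or KO draining 2 (0.06, the opposite sign).

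The genes of smallest p that stood higher in KO cells of the draining node were L3hypdh (0.40 ± 0.09), the adhesion gene Nectin3 (0.32 ± 0.08), the ESCRT gene Vps37b (0.82 ± 0.20), the potassium channel gene Kcna3 (0.39 ± 0.10) and Mylip, a ubiquitin ligase gene that targets the LDL receptor (0.45 ± 0.11). Mylip passed adjusted over the list alone within the 8 liver X receptor targets. The lower ones, beside Plk1, were the nuclear import gene Kpna2 (-0.53 ± 0.12), the proteasome gene Psmd1 (-0.55 ± 0.13), Fn3krp (-0.72 ± 0.18) and the DNA junction resolvase gene Gen1 (-0.85 ± 0.22). The smallest adjusted p in limma was 0.265, for the predicted gene Gm4951 (-0.91 ± 0.15).

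In the non-draining node, far from the tumour, KO cells again had higher immediate early genes and also a higher heat shock gene, Hsph1. Hsph1, which encodes a large heat shock protein, differed by 1.00 ± 0.17 (adjusted p = 0.333 in limma) and stood at a mean of 8.54 in KO and 7.53 in Het arrays on the log2 scale. It was not particular to this node, since its means in the draining node were 8.48 in KO and 7.92 in Het arrays. Immediate early genes were higher for 17 of 18 members with a median of 0.29, including Jun (0.57 ± 0.14), Klf2 (0.46 ± 0.13), the heat shock gene Hspa1a (1.16 ± 0.35) and Atf3 (0.52 ± 0.21). The list mean was 9.60 ± 0.14 in KO and 9.27 ± 0.13 in Het arrays (SD, n = 4 each), every KO array lay above every Het array, and the exact permutation p was 0.0286, the smallest that 4 against 4 arrays allow. The adjusted p was 1.58e-13 with the preset correlation but adjusted p = 0.280 with an estimated correlation, and the exact p adjusted over the 30 lists was 0.429. Of its members 3 passed adjusted over the list alone and 0 over all genes, and the median was 0.26 within arrays 1 and 2 and 0.25 within arrays 3 and 4.

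Endoplasmic reticulum stress genes in the non-draining node were higher in KO arrays for 15 of 15 members, with a median of 0.14 and examples in the chaperone genes Creld2 (0.46 ± 0.17) and Hsp90b1 (0.19 ± 0.10). The stress list had an exact permutation p of 0.0286, or 0.429 adjusted over the 30 lists, and adjusted p = 0.280 with an estimated correlation. The cDC1 identity genes were higher for 18 of 21 members (median 0.21), among them Snx22 (0.56 ± 0.19), the CD8 alpha gene Cd8a (0.40 ± 0.16), the inhibitory receptor gene Btla (0.42 ± 0.17) and Gcsam (0.41 ± 0.16). The cDC1 list had adjusted p = 0.381 with an estimated correlation. Markers of other cells differed between the same arrays. B cell markers were higher in KO for 12 of 12 members (median 0.33, Ms4a1 at 0.73 ± 0.26 and Pax5 at 0.51 ± 0.21). The B cell list had adjusted p = 0.280 with an estimated correlation. T cell markers were lower for 13 of 13 members (median -0.29, Cd5 at -0.62 ± 0.27 and Cd6 at -0.57 ± 0.25), with adjusted p = 0.433 with an estimated correlation. Within arrays 1 and 2 and within arrays 3 and 4, the medians were 0.08 and 0.27 for endoplasmic reticulum stress, 0.17 and 0.26 for cDC1 identity, 0.09 and 0.80 for B cell markers, and -0.53 and -0.03 for T cell markers. No member of these 4 lists passed over all genes or adjusted over the list alone. The B cell median was 0.55 without Het non-draining 2. The cDC1 median was 0.33 without Het non-draining 2, 0.11 without Het non-draining 3, 0.13 without Het non-draining 4 and 0.12 without KO non-draining 2. The T cell median was -0.54 without Het non-draining 2, -0.17 without Het non-draining 4, -0.13 without KO non-draining 2 and -0.44 without KO non-draining 3.

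Further lists passed in the non-draining node with the preset correlation only. Type I interferon response genes were higher in KO for 21 of 28 members (median 0.15), led by the chemokine gene Cxcl10 (0.67 ± 0.17), the only member to pass adjusted over the list alone, and by Irf7 (0.78 ± 0.28). Irf7 stood at -0.03 within arrays 1 and 2 and at 1.59 within arrays 3 and 4. The type I list had adjusted p = 0.433 with an estimated correlation. The type I median was -0.08 within arrays 1 and 2 and 0.45 within arrays 3 and 4, so its direction held only in the latter. Interferon gamma genes were higher for 9 of 13 (median 0.10, Cxcl9 at 0.40 ± 0.17). The interferon gamma list had adjusted p = 0.381 with an estimated correlation and medians of 0.20 and 0.10 within the numbers. MHC class II genes were higher for 11 of 11 (median 0.06, the class II transactivator gene Ciita at 0.34 ± 0.21). The class II list had adjusted p = 0.512 with an estimated correlation and medians of 0.05 and 0.11 within the numbers. Cell cycle genes were higher for 27 of 30 (median 0.17, Mcm6 at 0.50 ± 0.14 and Pcna at 0.23 ± 0.10). The cell cycle list had adjusted p = 0.433 with an estimated correlation and medians of 0.08 and 0.17 within the numbers. Beyond Cxcl10, no member of these 4 lists passed over all genes or adjusted over the list alone.

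Leaving out single arrays moved several of these values or ended their calls. A call could end without a smaller median: the MHC class II median was 0.056 with all arrays and between 0.062 and 0.118 without each array. The type I call ended without KO non-draining 4 (0.09), and its median was 0.10 without Het non-draining 3, 0.10 without Het non-draining 4, 0.27 without KO non-draining 2 and 0.08 without KO non-draining 3. The interferon gamma call ended without Het non-draining 1 (0.11), Het non-draining 2 (0.01), KO non-draining 1 (0.08), KO non-draining 3 (0.07) or KO non-draining 4 (0.06), and its median was 0.18 without KO non-draining 2. The MHC class II call ended without Het non-draining 3 (0.06), Het non-draining 4 (0.08), KO non-draining 1 (0.10) or KO non-draining 2 (0.07), and its median was 0.12 without Het non-draining 1, 0.09 without Het non-draining 2 and 0.09 without KO non-draining 3. The cell cycle median of KO against Het was 0.07 without Het non-draining 4 and 0.11 without KO non-draining 4.

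Other genes of smallest p in the non-draining node were the histone gene H3c4 (0.76 ± 0.15) and Mrgprb13 (0.41 ± 0.11) among those higher in KO. Those lower in KO were the protein kinase C gene Prkca (-0.81 ± 0.18), the zinc finger gene Ikzf5 (-0.46 ± 0.12), the adhesion gene Ceacam1 (-0.65 ± 0.18), Colq (-0.46 ± 0.13) and the intermediate filament gene Sync (-0.59 ± 0.16).

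**Figure D2:**
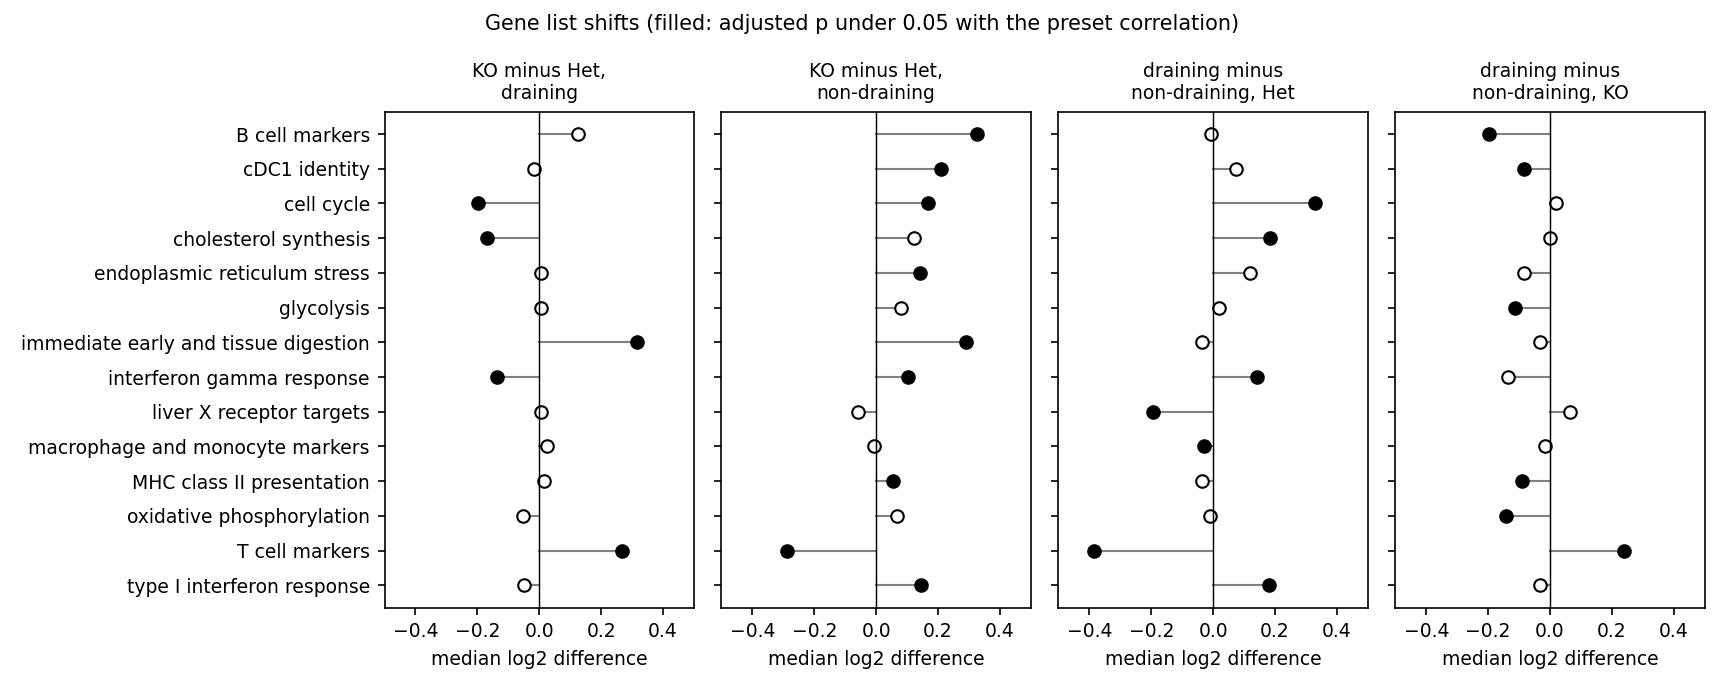
Median log2 difference of the 14 gene lists that passed in at least 1 comparison (horizontal axis, by list on the vertical axis) in the 4 simple comparisons, with filled points where camera with a preset correlation gave an adjusted p under 0.05. Immediate early genes stood at 0.32 and 0.29 in KO against Het cells of the draining and non-draining nodes, and T cell markers at 0.27 and -0.29.

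Over both nodes, immediate early genes again had the smallest p among the lists. Hsph1 had the smallest p among single genes, with a log2 difference of 0.78 ± 0.12 and an adjusted p of 0.103 in limma. Its adjusted p ranged from 0.0315 with the replicate number as a fixed block, where it passed, to 1.00 within arrays 1 and 2. It did not pass with a random block of genotype and number (adjusted p = 0.358) or with the 2 sets of arrays as a block (adjusted p = 0.0596), a setting chosen after the results were seen. Immediate early genes were higher for 18 of 18 members (median 0.29), of which 12 passed adjusted over the list alone and 0 over all genes. Among them Jun (0.50 ± 0.10), Klf2 (0.38 ± 0.09), Hspa1a (0.97 ± 0.25) and Dnajb1 (0.42 ± 0.12) had the smallest p. The adjusted p of the list was 1.24e-20 with the preset correlation but adjusted p = 0.0801 with an estimated correlation, and an exact permutation of genotype within nodes gave 0.00204, or 0.0612 adjusted over the 30 lists. With the arrays of a genotype and number kept together the exact p was 0.0286, the smallest that 4 against 4 pairs allow, or 0.857 adjusted over the 30 lists. The medians were 0.26 within arrays 1 and 2 and 0.34 within arrays 3 and 4. The arrestin family gene Arrdc3 (0.45 ± 0.10) and the GTPase gene Rhob (0.60 ± 0.15) were also among the higher genes of smallest p. Lower in KO were Ceacam1 (-0.60 ± 0.12), Psmd1 (-0.43 ± 0.09), the costimulatory receptor gene Tnfrsf9 (-0.69 ± 0.15), Sync (-0.52 ± 0.12) and the proteasome adaptor gene Ecpas (-0.28 ± 0.07), and Tnfrsf9 passed adjusted over the list alone among 25 dendritic cell maturation genes.

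B cell markers were higher in KO arrays for 11 of 12 members over both nodes (median 0.32, Fcer2a at 0.52 ± 0.22 and Cd79a at 0.45 ± 0.21). The B cell list had adjusted p = 0.543 with an estimated correlation and medians of 0.12 and 0.39 within arrays 1 and 2 and within arrays 3 and 4. The cDC1 identity genes were higher for 18 of 21 (median 0.12, Snx22 at 0.38 ± 0.13, against Ly75 at -0.27 ± 0.12). The cDC1 list had adjusted p = 0.658 with an estimated correlation and medians of 0.07 and 0.18 within the numbers. Endoplasmic reticulum stress genes were higher for 14 of 15 (median 0.07, Herpud1 at 0.24 ± 0.09). The stress list had adjusted p = 0.658 with an estimated correlation and medians of 0.02 and 0.16 within the numbers. No member of these 3 lists passed over all genes or adjusted over the list alone. The cDC1 call ended without Het draining 1 (0.14), KO draining 3 (0.08), Het non-draining 3 (0.08) or KO non-draining 2 (0.07), and its median was 0.07 without KO draining 1, 0.19 without Het non-draining 2 and 0.07 without Het non-draining 4. The endoplasmic reticulum stress call ended without Het draining 4 (0.06), KO draining 2 (0.04) or KO draining 3 (0.06).

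In Het cells, cell cycle genes were higher in the draining than in the non-draining node. All 30 measured members stood higher, with a median log2 difference of 0.33, and 10 passed adjusted over the list alone while 0 passed over all genes. They included the mitotic checkpoint kinase gene Bub1 (0.67 ± 0.15), Top2a (0.59 ± 0.15), the mitotic kinase gene Aurkb (0.60 ± 0.17) and Cdk1 (0.56 ± 0.15). The list mean was 6.95 ± 0.21 in draining and 6.55 ± 0.14 in non-draining arrays (SD, n = 4 each), and the exact two-sided permutation p was 0.0571. This was the only list of the 7 comparisons that passed both ways, with adjusted p = 4.54e-24 with the preset correlation and adjusted p = 0.0497 with an estimated correlation. The replicate numbers were taken to pair these 8 arrays, which the labels do not state. Only 2 of the 4 draining arrays correlated best with their own number, and the split of arrays 1 and 2 from 3 and 4 could give this without pairing. With the replicate number as a block the list had adjusted p = 0.109 with an estimated correlation, so that the call was lost there. With the 2 sets of arrays as a block, a setting chosen after the results were seen, it was kept (adjusted p = 0.0472 with an estimated correlation). The medians were 0.55 within arrays 1 and 2 and 0.31 within arrays 3 and 4. Among single genes outside the list, H3c4 (0.77 ± 0.15), Gen1 (1.06 ± 0.22), Tpst1 (0.46 ± 0.09) and Sdad1 (0.59 ± 0.14) were the higher ones of smallest p, with a smallest adjusted p of 0.794 in limma. The H3c4 value rests on the same Het non-draining arrays as its value in KO against Het cells above. The lower ones were the keratin gene Krt77 (-0.43 ± 0.11), the AP-1 gene Fosl2 (-0.75 ± 0.19), Cstad (-0.56 ± 0.14), the phosphatase gene Ptpn5 (-0.32 ± 0.09) and the mitochondrial carrier gene Slc25a33 (-0.65 ± 0.18).

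T cell markers were lower in the draining node of Het mice for 12 of 13 members (median -0.39, Ccr4 at -0.49 ± 0.24 and Cd5 at -0.52 ± 0.27). The T cell list had adjusted p = 0.528 with an estimated correlation and medians of -0.38 and -0.22 within the numbers. Type I interferon genes were higher for 22 of 28 (median 0.18, the antiviral kinase gene Eif2ak2 at 0.49 ± 0.16 and Cxcl10 at 0.53 ± 0.17). The type I list had adjusted p = 0.458 with an estimated correlation and medians of 0.06 and 0.27 within the numbers. Interferon gamma genes were higher for 10 of 13 (median 0.14, Iigp1 at 0.77 ± 0.27 and Cxcl9 at 0.42 ± 0.17). The interferon gamma list had adjusted p = 0.361 with an estimated correlation and medians of 0.11 and 0.10 within the numbers. Cholesterol synthesis genes were higher for 16 of 16 (median 0.18), of which Cyp51 (0.42 ± 0.11) passed adjusted over the list alone. The cholesterol list had adjusted p = 0.528 with an estimated correlation and medians of 0.21 and 0.18 within the numbers. Liver X receptor targets were lower for 7 of 8 (median -0.19), and Mylip (-0.34 ± 0.11) and the cholesterol exporter gene Abca1 (-0.23 ± 0.08) passed adjusted over the list alone. The liver X receptor list had adjusted p = 0.458 with an estimated correlation and medians of -0.30 and -0.04 within the numbers. Macrophage and monocyte markers had a median of -0.03 with 9 of 15 lower, led by Cd14 (-0.57 ± 0.20) and Lyz2 (-0.53 ± 0.20). The macrophage list had an exact permutation p of 0.0286, or 0.429 adjusted over the 30 lists. It had adjusted p = 0.528 with an estimated correlation and medians of -0.04 and -0.10 within the numbers. No member of these lists passed over all genes, and none but those named passed adjusted over the list alone.

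Leaving out single arrays moved several of these Het values. The T cell median was -0.18 without Het draining 1, and the type I median 0.10 without Het non-draining 4. The cholesterol call ended without Het draining 3 (0.08), and its median was 0.28 without Het draining 1 and 0.12 without Het non-draining 2. The interferon gamma call ended without Het draining 3 (0.08) or Het draining 4 (0.01), and its median was 0.22 without Het draining 1 and 0.03 without Het non-draining 2. The liver X receptor call ended without Het draining 1 (-0.13), Het draining 2 (-0.11), Het non-draining 1 (-0.15) or Het non-draining 4 (-0.15). The macrophage call ended without Het draining 2 (-0.01), Het draining 3 (-0.03), Het draining 4 (-0.07), Het non-draining 1 (-0.02) or Het non-draining 3 (-0.01), and its median was -0.07 without Het draining 1 and -0.08 without Het non-draining 2. With the replicate number as a block, cDC1 identity and cDC2 marker genes also passed with the preset correlation in Het cells (adjusted p = 0.0253 each), and neither did with an estimated correlation.

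**Figure D3:**
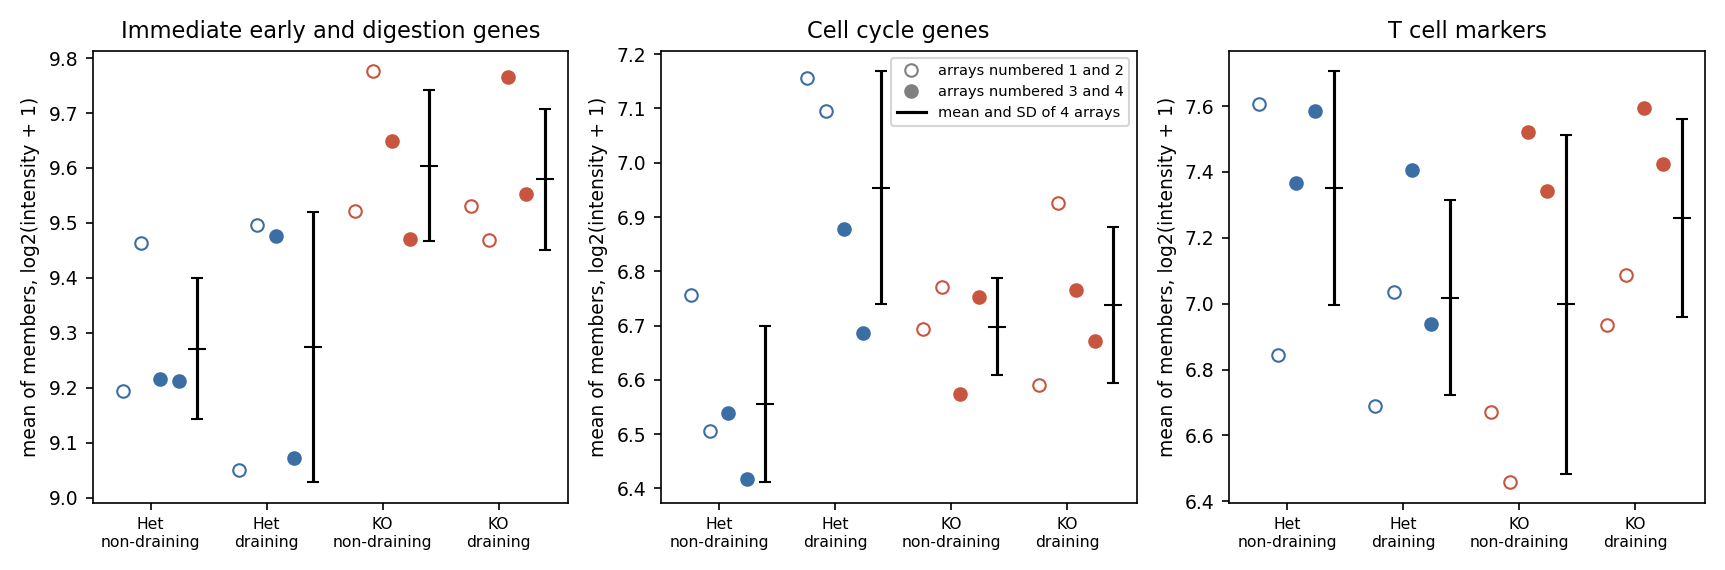
Mean log2(intensity + 1) of the members of 3 lists (vertical axis) per array in the 4 groups (horizontal axis), with arrays numbered 1 and 2 as open points, arrays numbered 3 and 4 as filled points, and the mean and SD of 4 arrays as bars. Immediate early means were 9.60 in KO and 9.27 in Het arrays of the non-draining node, and cell cycle means 6.95 in draining and 6.55 in non-draining Het arrays.

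In KO cells, the draining and non-draining nodes differed in 421 genes at an unadjusted p under 0.05, a count of 809 without KO draining 3 and 663 without KO draining 4. The smallest adjusted p in limma was 1.00. The higher genes of smallest p in the draining node were Sdr42e1 (0.38 ± 0.09), the centromere gene Cenpn (0.55 ± 0.13), the phospholipid synthesis gene Selenoi (0.38 ± 0.10), BC052040 (0.76 ± 0.22) and the RNA methylation gene Zc3h13 (0.37 ± 0.11). The lower ones were the ATP synthase assembly gene Atpaf1 (-0.65 ± 0.16), the homeobox gene Pbx4 (-0.36 ± 0.10), Slc35e1 (-0.32 ± 0.09), Krtap8-1 (-0.29 ± 0.09) and the Mediator gene Med26 (-0.35 ± 0.11). T cell markers were higher in the draining node for 13 of 13 members (median 0.24, Cd5 at 0.45 ± 0.27), and B cell markers lower for 11 of 12 (median -0.20, the kinase gene Blk at -0.30 ± 0.12). Oxidative phosphorylation genes were lower for 21 of 22 (median -0.14, the complex I gene Ndufb3 at -0.33 ± 0.21) and glycolysis genes for 10 of 11 (median -0.11, Pgk1 at -0.19 ± 0.12). MHC class II genes were lower for 11 of 11 (median -0.09, H2-Eb1 at -0.10 ± 0.08) and cDC1 identity genes for 18 of 21 (median -0.09, Btla at -0.31 ± 0.17). All 6 lists passed with the preset correlation, and each had adjusted p = 0.797 with an estimated correlation. No member passed over all genes or adjusted over the list alone.

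Within arrays 1 and 2 and within arrays 3 and 4 of the KO mice, the medians between nodes were 0.42 and 0.09 for T cell markers, -0.20 and -0.25 for B cell markers, -0.26 and -0.02 for oxidative phosphorylation, -0.24 and -0.03 for glycolysis, -0.25 and -0.01 for MHC class II, and -0.20 and 0.03 for cDC1 identity. Every KO call between nodes ended without some array. For T cell markers these were KO draining 3 (0.20), KO draining 4 (0.19), KO non-draining 1 (0.13) and KO non-draining 2 (0.08), and the median was 0.49 without KO non-draining 3 and 0.36 without KO non-draining 4. For B cell markers it was KO non-draining 4 (-0.17), and the median was -0.12 without KO draining 2. For oxidative phosphorylation these were KO draining 1 (-0.08), KO draining 2 (-0.0014) and KO non-draining 4 (-0.07), and the median was -0.24 without KO draining 3, -0.24 without KO draining 4 and -0.25 without KO non-draining 2. For glycolysis these were KO draining 1 (-0.09), KO draining 2 (-0.10), KO draining 4 (-0.14), KO non-draining 2 (-0.12) and KO non-draining 4 (-0.17). For MHC class II these were KO draining 1 (-0.07), KO draining 2 (-0.08), KO draining 4 (-0.07), KO non-draining 1 (-0.12) and KO non-draining 2 (-0.02), and the median was -0.16 without KO draining 3. For cDC1 identity these were KO draining 2 (-0.10), KO draining 4 (-0.06), KO non-draining 1 (-0.08) and KO non-draining 2 (0.02), and the median was -0.14 without KO non-draining 3.

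Over both genotypes, cell cycle genes were higher in the draining node for 30 of 30 members, with a median of 0.21 and 3 members that passed adjusted over the list alone. Bub1 (0.46 ± 0.11), the ribonucleotide reductase gene Rrm2 (0.60 ± 0.14), the cyclin gene Ccna2 (0.55 ± 0.17) and Mcm3 (0.32 ± 0.11) led the list, which had adjusted p = 0.284 with an estimated correlation. Its exact permutation p was 0.0314, or 0.0391 with the arrays of a genotype and number kept together. Adjusted over the 30 lists these exact p values were 0.889 and 0.854. Cell cycle medians were 0.26 and 0.18 within arrays 1 and 2 and within arrays 3 and 4. Cholesterol synthesis genes were higher for 15 of 16 (median 0.10, Cyp51 at 0.21 ± 0.07 and Nsdhl at 0.22 ± 0.10). The cholesterol list had adjusted p = 0.830 with an estimated correlation and medians of 0.10 and 0.13 within the numbers. The cholesterol call ended without Het draining 3 (0.06), KO draining 1 (0.07), KO draining 3 (0.06), KO draining 4 (0.05), Het non-draining 2 (0.08) or KO non-draining 2 (0.04), and its median was 0.20 without KO draining 2. The other higher genes of smallest p were Cenpn (0.41 ± 0.09), H3c4 (0.43 ± 0.11) and Selenoi (0.27 ± 0.07). The lower ones were Cstad (-0.41 ± 0.10), the lipopolysaccharide co-receptor gene Cd14 (-0.53 ± 0.14), the mismatch repair gene Mlh3 (-0.38 ± 0.10), Slc25a33 (-0.45 ± 0.12) and Atpaf1 (-0.39 ± 0.11). Cd14 was also the only member of the macrophage list to pass adjusted over the list alone, and none of these genes passed over all genes (smallest adjusted p = 0.998 in limma).

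The interaction asked whether the difference between nodes depended on genotype, and a positive value means a higher draining against non-draining difference in KO than in Het cells. Cell cycle genes were lower by this measure for 27 of 30 members, with a median of -0.37 and examples in Plk1 (-1.03 ± 0.30), Top2a (-0.62 ± 0.21) and Cdk1 (-0.55 ± 0.22). For any list, T cell markers included, the interaction and the comparisons above use the same 4 group means, so they are not independent findings. For the cell cycle list these means were 6.555 in Het non-draining, 6.954 in Het draining, 6.698 in KO non-draining and 6.738 in KO draining arrays. The list passed with the preset correlation (adjusted p = 2.20e-12) but had adjusted p = 0.205 with an estimated correlation, an exact permutation p of 0.0882 (0.0286 with the arrays of a genotype and number kept together, or 0.429 adjusted over the 30 lists), and medians of -0.44 and -0.25 within arrays 1 and 2 and within arrays 3 and 4. T cell markers were higher for 13 of 13 (median 0.69, Cd5 at 0.97 ± 0.38 and Ccr4 at 0.76 ± 0.33). The T cell list had adjusted p = 0.510 with an estimated correlation and medians of 0.72 and 0.30 within the numbers. Interferon gamma genes were lower for 12 of 13 (median -0.18, Iigp1 at -1.01 ± 0.38 and the checkpoint ligand gene Cd274 at -0.57 ± 0.24). The interferon gamma list had adjusted p = 0.205 with an estimated correlation and medians of -0.21 and -0.29 within the numbers. Its exact permutation p was 0.0429, or 0.816 adjusted over the 30 lists (0.0286 and adjusted 0.429 with those arrays kept together). Type I interferon genes were lower for 21 of 28 (median -0.15), of which Cxcl10 (-0.93 ± 0.25) passed adjusted over the list alone, also within the list of cytokines and chemokines. The type I list had adjusted p = 0.604 with an estimated correlation and medians of 0.21 and -0.51 within the numbers, so that the direction held only in arrays 3 and 4. The T cell median was 0.43 without KO draining 3 and 0.36 without KO non-draining 2. The interferon gamma median was -0.28 without Het draining 2, -0.31 without KO draining 1 and -0.28 without KO non-draining 2. The type I call ended without KO non-draining 4 (-0.14), and its median was -0.26 without Het draining 1, -0.23 without Het draining 3, -0.25 without KO draining 1, -0.26 without KO draining 2, -0.26 without Het non-draining 2 and -0.32 without KO non-draining 2.

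The other 5 lists passed in the interaction with the preset correlation only. The cDC1 identity genes had a median of -0.16 (18 of 21 lower), cholesterol synthesis genes -0.19 (13 of 16 lower) and B cell markers -0.22 (10 of 12 lower), and each of these 3 lists had adjusted p = 0.682 with an estimated correlation. Oxidative phosphorylation genes had a median of -0.15 (20 of 22 lower) with adjusted p = 0.70 with an estimated correlation, and liver X receptor targets 0.21 (5 of 8 higher) with adjusted p = 0.510 with an estimated correlation. Examples were Btla (-0.45 ± 0.23), Cyp51 (-0.42 ± 0.15), Cd79b (-0.50 ± 0.25), Sdhc (-0.19 ± 0.17) and Mylip (0.49 ± 0.16), and no member passed over all genes or adjusted over the list alone. With the replicate number as a block, B cell markers and liver X receptor targets no longer passed (adjusted p = 0.058 and 0.0994 in limma camera). Within arrays 1 and 2 and within arrays 3 and 4, the medians were -0.20 and -0.14 for cDC1 identity, -0.32 and -0.11 for cholesterol, 0.05 and -0.61 for B cell markers, -0.30 and 0.04 for oxidative phosphorylation, and 0.22 and 0.0061 for liver X receptor targets. The cDC1 call ended without KO non-draining 2 (-0.16), and the median was -0.26 without KO draining 1, -0.24 without KO draining 3 and -0.26 without Het non-draining 2. The cholesterol call ended without Het draining 3 (-0.12), KO draining 2 (-0.05), Het non-draining 2 (-0.17), KO non-draining 3 (-0.17) or KO non-draining 4 (-0.12), and the median was -0.30 without Het draining 1, -0.31 without KO draining 4 and -0.29 without KO non-draining 2. The B cell call ended without Het draining 4 (-0.06), KO draining 1 (-0.20), KO draining 2 (-0.16), Het non-draining 1 (-0.14), Het non-draining 3 (-0.20), Het non-draining 4 (-0.24), KO non-draining 3 (-0.19) or KO non-draining 4 (-0.15), and the median was -0.42 without Het non-draining 2. The oxidative phosphorylation call ended without Het draining 2 (-0.12), Het draining 3 (-0.06), KO draining 1 (-0.08), KO draining 2 (-0.03, the test turning to the opposite direction), Het non-draining 1 (-0.09), Het non-draining 2 (-0.13), KO non-draining 3 (-0.09) or KO non-draining 4 (-0.06). Its median was -0.25 without KO draining 3, -0.24 without KO draining 4 and -0.26 without KO non-draining 2. The liver X receptor call ended without Het draining 1 (0.14), Het draining 2 (0.18), KO draining 1 (0.10), KO draining 3 (0.20), KO draining 4 (0.17), Het non-draining 1 (0.23), Het non-draining 4 (0.18), KO non-draining 1 (0.14), KO non-draining 2 (0.23) or KO non-draining 3 (0.22).

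The gene of smallest p in the interaction was Gm4951 (-0.92 ± 0.21, adjusted p of 1.00 in limma). With predicted genes left out, those of smallest p were the circadian gene Ciart (1.08 ± 0.29), Vps37b (0.99 ± 0.28), Secisbp2l (0.66 ± 0.19), the phosphatase gene Dusp14 (0.63 ± 0.19) and Nlrc3 (0.65 ± 0.19) with higher values. Those with lower values were the cell cycle phosphatase gene Cdc25a (-0.73 ± 0.18), Gpr33 (-0.98 ± 0.25), Cxcl10, the sterol-binding gene Stard5 (-0.57 ± 0.16) and the spindle gene Tacc3 (-0.56 ± 0.16), and none of these passed over all genes.

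The remaining 15 lists, with the neighbours of Wdfy4 given above, passed in none of the 7 comparisons in the fit without a block. Maturation, lysosome and cDC2 lists passed in some comparisons once the replicate number was a block, with the preset correlation only. Cross-presentation and vesicle traffic genes, the list closest to the function of WDFY4, had medians between -0.08 and 0.03 and a smallest adjusted p of 0.183 in limma camera. MHC class I processing genes had medians between -0.10 and 0.04 (smallest adjusted p of 0.11 in limma camera) and the other BEACH domain genes between 0.0036 and 0.07 (0.287). Among BEACH genes, Nbeal2 stood at 0.24 ± 0.14, Lyst at 0.12 ± 0.15 and Lrba at 0.07 ± 0.11 in KO against Het cells of the draining node. Dendritic cell maturation genes lay between -0.08 and 0.05 (0.0959), cytokines and chemokines for T cells between -0.06 and 0.07 (0.0899), where Cxcl10 passed adjusted over the list alone in the non-draining node, and lysosome genes between -0.11 and -0.03 (0.0521). Skin migratory dendritic cell markers lay between -0.06 and 0.08 (0.11), but the tight junction gene Cldn1 (0.59 ± 0.16 in the draining node and 0.37 ± 0.11 over both nodes) passed adjusted over the list alone in KO against Het cells, as did the Langerhans cell gene Cd207 over both nodes (0.43 ± 0.13). These calls were not adjusted across lists or comparisons, and neither gene passed over all genes. Markers of other cells had medians between -0.21 and 0.10 for cDC2 (0.0657), -0.07 and 0.15 for plasmacytoid dendritic cells (0.385), -0.03 and 0.13 for NK and cytotoxic cells (0.0725). They lay between -0.07 and 0.06 for neutrophils (0.10), -0.09 and 0.05 for plasma cells (0.312) and 0.0048 and 0.08 for stromal cells (0.224). Of the erythroid list only Alas2 was measured, with differences between -0.18 and 0.05 (0.225). Sex-linked genes lay between -0.08 and 0.04 (0.385). All 16 arrays had Xist between 10.2 and 10.7 and the Y-linked genes Kdm5d, Uty and Eif2s3y between 2.95 and 3.71 on the log2 scale.

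The arrays also differed in a way that the groups do not explain. The first principal component of all genes held 30.7% of the variance and placed all 8 arrays numbered 1 and 2 (highest score -3.09) below all 8 arrays numbered 3 and 4 (lowest score 4.65). This grouping of the arrays was chosen after these scores were seen, so its differences describe the arrays and were not tested on other data. KO draining 2 lay farthest out, with a score of -44.1 and a median correlation with the other arrays of 0.976 where the next lowest was 0.984. Between arrays 3 and 4 and arrays 1 and 2, 2359 genes differed in limma, 1501 higher and 858 lower in arrays 3 and 4. T cell markers were among them (median 0.40, 7 of 13 members higher and 0 lower), as were oxidative phosphorylation genes (0.27, 8 of 22 higher) and dendritic cell maturation genes (0.33, 8 of 25 higher and 2 lower), while cDC1 identity genes had a median of -0.20 with 7 of 21 lower and 2 higher. The labels do not say what the numbers stand for, and each of the 4 groups holds 2 arrays on either side.

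**Figure D4:**
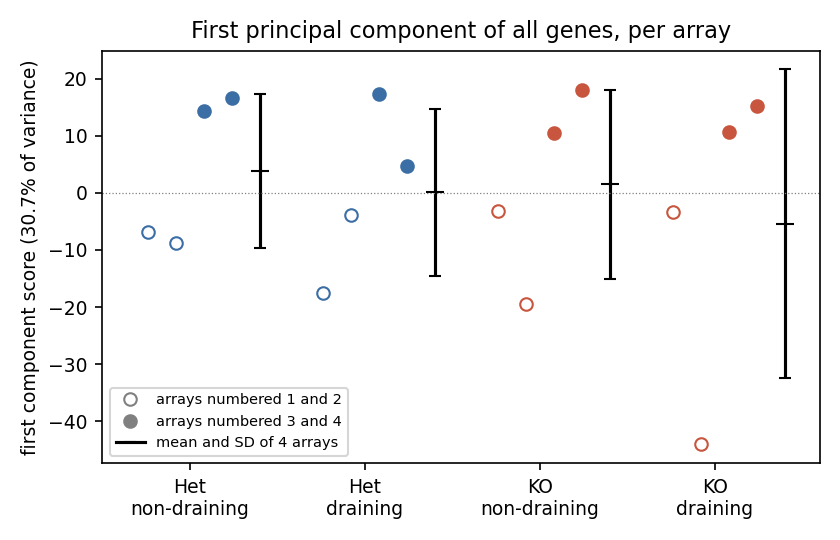
Score of each array on the first principal component (vertical axis, no unit) in the 4 groups (horizontal axis), with arrays numbered 1 and 2 as open points, arrays numbered 3 and 4 as filled points, and the mean and SD of 4 arrays as bars. The open points lie at or below -3.09 and the filled points at or above 4.65 in every group, and KO draining 2 lies at -44.1.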

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

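The tests of heat shock genes and of T and B cell RNA on the immediate early pattern, and of the intensity distribution on the array numbers, were written before their results were seen; all other tests in this part, the heat shock list and the counts of splits were chosen after the results were seen. Arrays that stood apart from the other 3 of their group were found in 21 of 344 groups tested, where chance marks about 1 in 20 groups, or 17.

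Immediate early genes were higher in KO arrays over both nodes, by 0.319 on the log2 scale in the mean of the list, with a two-sided exact permutation p of 0.00204. A single array as the source is argued against, since the difference was at least 0.28 without each array in turn (highest 0.36, largest exact p 0.00776 without KO draining 3) and at least 0.27 without each pair of a genotype and number (largest exact p 0.0571 for pairs kept together). After the marker means of T and B cells were taken out, with slopes fitted within the groups, the difference was 0.32 (exact p 0.00204, or 0.0286 with pairs kept together). This argues against B cell RNA, whose markers differed by 0.268 between KO and Het arrays over both nodes. For T cell RNA the test decides little, since those markers differed by only -0.055 there. Chance is excluded only for this list taken alone, with 5 of 2450 splits of genotype within nodes as large (highest other 0.326) and 1 of 35 splits with pairs kept together (highest other 0.304), but the list was 1 of 30 and its exact p adjusted over them was 0.0612 and 0.857. Digestion and handling that differed between KO and Het mice cannot be told apart from an effect of Wdfy4, because 15 heat shock genes outside the list differed by 0.060 (exact p 0.338, or 0.543 with pairs kept together), above the bound of 0 that would have argued against handling and without a p under 0.05. Hsph1 was left out of the 15 genes because its value had already been seen, and Hspa1a belongs to the immediate early list. Whether these genes reflect such stress was therefore not tested. Of the 15 genes 11 were higher in KO, with Hsp90aa1 at 0.20 and Hspd1 at 0.34 (unadjusted p 0.0183 and 0.0346 in limma, adjusted 1.00 each), and Chordc1 at -0.26 was the lowest. This count decides nothing, since the genes may vary together and their mean did not differ beyond its spread.

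Cell cycle genes were higher in Het draining than Het non-draining arrays, by 0.399 in the mean of the list with a two-sided exact permutation p of 0.0571. A single array is argued against, since the difference was at least 0.33 without each array in turn (lowest without Het draining 1, highest 0.49). Chance cannot be excluded, with 2 of 35 splits as large and a highest other split of 0.434. Among the 8 splits that part all 4 numbered pairs only the real one was as large (highest other 0.27), and the other splits leave some pairs together. The smallest share that these 8 splits allow is 1 of 8, so they cannot exclude chance either. The draining array had the higher list mean in all 4 pairs (7.16 against 6.76, 7.09 against 6.51, 6.88 against 6.54, 6.69 against 6.42). T cells that divide and were sorted along cannot be told apart from dividing cDC1 or their precursors: T cell markers differed by -0.33 in the mean, which met the bound of at most 0 written for that test, but not by more than its spread (exact p 0.229). An effect of the tumour-draining node remains open and was not tested apart from these.

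Arrays numbered 1 and 2 differed from those numbered 3 and 4 in 2359 genes over all groups, a grouping chosen after the first principal component was seen. The intensity distribution is argued against as the whole source, since 2018 genes still differed after repeated quantile normalization. T cell RNA diluting that of cDC1 cannot be told apart from other sources, since 2 cDC1 identity genes, Batf3 at 0.54 and Zbtb46 at 0.27, were called higher in arrays 3 and 4, where 3 were set as the bound, while Tlr3 at -0.81, Cadm1 at -0.44 and Xcr1 at -0.44 were lower. An unrecorded processing batch may underlie the split and cannot be told apart from separate cohorts of mice, since 0 label fields name a batch or a date. No biological explanation was tested.

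Counts of genes at an unadjusted p under 0.05 were set against other splits of the same arrays, or for the interaction against shuffled residuals. Chance could not be excluded in any comparison, but these counts could hardly exclude it. The real groups hold arrays 1 and 2 and arrays 3 and 4 in equal number. Many of the splits do not, and so carry the difference between these sets. Apart from the 8 Het splits that part all pairs, no reference of balanced splits alone was made. For KO against Het in the draining node 29 of 35 splits gave at least the real 675 (highest other 3680), and in the non-draining node 21 of 35 gave at least 494 (highest other 2579). For draining against non-draining, 19 of 35 splits gave at least 655 in Het cells (highest other 2636) and 34 of 35 at least 421 in KO cells (highest other 4004). Among the 8 Het splits that part all pairs, 2 gave as many as the real one (highest other 746). Of 100 splits each, 76 gave at least 463 for the interaction (highest other 4862), 69 at least 696 for genotype over both nodes (highest other 2942) and 69 at least 610 for node over both genotypes (highest other 4690). In 3 of the 4 simple comparisons, all but KO against Het in the draining node, the highest split was that of arrays 1 and 2 against 3 and 4, which points to a structure of the samples. At an adjusted p under 0.05 in limma, splits called up to 693 genes and the shuffled residuals of the interaction up to 901, where the real groups called 0.

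The difference between nodes differed between genotypes for 9 lists by the interaction with the preset correlation, and for none of them with an estimated correlation. The medians were -0.37 for cell cycle, 0.69 for T cell markers, -0.18 for interferon gamma response, -0.15 for type I interferon response, -0.16 for cDC1 identity, -0.19 for cholesterol synthesis, -0.15 for oxidative phosphorylation, 0.21 for liver X receptor targets and -0.22 for B cell markers.

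KO draining 2 was the array apart in 5 of the 21 groups. It was lowest on the log2 scale for Psmd1 (8.24, others 8.77 to 8.81), for Cxcl10 (6.20, others 6.77 to 6.87), and for the list means of cholesterol synthesis (6.86, others 7.55 to 7.67), cytokines and chemokines (8.02, others 8.48 to 8.55) and lysosome genes (8.12, others 8.50 to 8.55). Gen1 was lowest in Het non-draining 2 (3.70, others 4.35 to 4.46) and highest in KO non-draining 1 (5.19, others 4.13 to 4.22). Ceacam1 was lowest in Het draining 2 (5.83, others 6.35 to 6.43), Krt77 in Het draining 1 (4.78, others 5.10 to 5.14), Sdr42e1 in Het non-draining 1 (4.67, others 4.84 to 4.86), Tacc3 in KO draining 1 (6.65, others 7.06 to 7.08) and Cd14 in KO non-draining 1 (7.54, others 7.81 to 7.84). Bub1 was highest in KO draining 4 (5.63, others 5.15 to 5.16), Slc35e1 in Het non-draining 1 (7.16, others 6.82 to 6.88) and Klf2 in KO non-draining 2 (8.80, others 8.58 to 8.62). Among list means, B cell markers were highest in Het draining 4 (6.26, others 5.64 to 5.73), immediate early genes in Het non-draining 2 (9.46, others 9.19 to 9.22), stromal markers in Het non-draining 4 (5.93, others 5.74 to 5.76), plasma cell markers in Het non-draining 3 (5.87, others 5.45 to 5.49) and skin dendritic cell markers in Het draining 4 (8.97, others 8.81 to 8.83). The erythroid gene Alas2 was lowest in KO non-draining 4 (4.44, others 4.61 to 4.63).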

How the results depend on the processing

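The fits on arrays 1 and 2 alone, on arrays 3 and 4 alone, with these sets as a block and with the block within the compared groups, and the exact permutations of list means, were chosen after the results were seen; the cause was not tested for any change given here unless a smaller number of arrays is named. The count of genes past the threshold was 0 in limma in every comparison and without each array in turn. It became 4 (KO against Het, draining), 2 (non-draining), 1 (draining against non-draining, KO) and 5 (KO against Het, both nodes) with arrays 3 and 4 alone, where Irf7 stood at 1.59 (adjusted p = 0.030) in the non-draining node, and 1 with the replicate number as a fixed block (KO against Het, both nodes, Hsph1) but 0 with the random block and the block of the 2 array sets. At an unadjusted p under 0.05, the counts ranged, over alternatives that tested the same 19938 genes, from 434 to 1535, 422 to 1310, 582 to 1188, 338 to 861, 404 to 827, 458 to 2021 and 528 to 998 (675, 494, 655, 421, 463, 696 and 610 as reported, in the order of the comparisons given next), with 1238 for KO against Het, non-draining, under array weights. Of 5270 alternative values of 228 named gene results, 5255 kept direction and side of the threshold, 2 were stronger, 0 weaker and 13 reversed. No named gene passed over all genes, so none could become weaker, and keeping its side meant staying above the threshold. The genes were picked for small p in these same arrays, so kept directions were partly built in and do not show that the differences are real. With arrays 3 and 4 alone the reversed values were Msmo1 0.0037 (KO against Het, draining), Cd3g 0.044 (non-draining), Nsdhl 0.012 (interaction) and, for draining against non-draining in KO, Cd6 -0.11, Clec9a 0.093, Gcsam 0.10, H2-DMa 0.16, H2-Eb1 0.012 and H2-Oa 0.16. With arrays 1 and 2 alone they were Irf7 -0.027 (non-draining) and Pax5 0.22 (interaction), with array weights H2-Oa 0.034, and with the mean of probe sets Ighm 0.33.

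The lists called were 5, 9, 7, 6, 9, 4 and 2 for KO against Het in the draining and the non-draining node, draining against non-draining in Het and in KO, the interaction, and the genotype and node means. They became 0 in all 7 with the exact permutation, 0 in the last 3 with the arrays of a genotype and number kept together, and 0 with an estimated correlation except 1 in Het. With arrays 1 and 2 alone they became 3 (KO against Het, draining), 3 (non-draining), 4 (interaction) and 9 (node mean), and with arrays 3 and 4 alone 9 (KO against Het, draining), 2 (draining against non-draining, KO), 10 (genotype mean) and 5 (node mean). Without dim genes draining against non-draining in KO had 2. Leaving out each array gave, in the same order, 3 to 9, 8 to 12, 5 to 10, 2 to 7, 5 to 9, 3 to 9 and 2 to 9. Of 708 alternative values of 42 list calls, 518 kept direction and call, 182 lost the call, 41 of them with the estimated correlation, and 8 reversed. Reversed were cholesterol synthesis in KO against Het of the draining node (0.057 without KO draining 2, range -0.25 to 0.057 without each array) and oxidative phosphorylation in the interaction (-0.031 by a turned test without KO draining 2, range -0.26 to -0.031). With arrays 1 and 2 alone type I interferon genes reversed in the non-draining node (-0.079) and the interaction (0.21), as did B cell markers in the interaction (0.052). With arrays 3 and 4 alone cDC1 identity (0.025) and MHC class II (-0.011, by a turned test) reversed between nodes in KO, and oxidative phosphorylation in the interaction (0.039).

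Same-numbered arrays correlated between -0.014 and 0.481 for the nodes in KO, between -0.056 and 0.420 for KO and Het in the draining node and between 0.017 and 0.351 in the non-draining node, with 2, 1 and 2 of 4 arrays closest to their own number, so the single numbers were not taken to pair arrays, although all groups share the split of arrays 1 and 2 from 3 and 4. With the replicate block the lists called were 5, 10, 9, 6, 7, 6 and 9 with the preset correlation and 0 in all 7 with an estimated one. The lists gained were maturation in the non-draining node (adjusted p = 0.0194 in limma camera) and the genotype mean (0.0181), lysosome in the genotype mean (0.0181), and B cell, cDC2, glycolysis, lysosome, macrophage and MHC class II lists (0.0426) and oxidative phosphorylation (0.0226) in the node mean. Of these, lysosome in the genotype mean (0.0307) and oxidative phosphorylation (0.0183) also passed with the 2 array sets as a block. The blocked fit changed no other call than these and those given with the results. A random block of genotype and number had a correlation of 0.198. Signal over background limits the dim genes, and 4 arrays per group limit all others.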

Other observations

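The choice of these comparisons was made after the results were seen. The difference between KO and Het cells in the draining node and that in the non-draining node correlated across genes with r = 0.121, where 21 of 100 splits gave as large a value, and the node difference in Het and that in KO cells with r = 0.0778, where 34 of 100 did. Genes are not independent replicates. Plasma cell genes differed widely between arrays, with Jchain at -1.11 ± 0.64 in KO against Het cells over both nodes (adjusted p of 1.00 in limma), and the chemokine gene Ccl3, which attracts T cells, stood at 0.69 ± 0.27 in KO against Het cells of the draining node (adjusted p of 1.00 in limma). With arrays 3 and 4 alone, a setting chosen after the results were seen, the genes past the threshold included the lectin gene Clec4b2 at 1.16 and the transcription factor gene Stat4 at -1.08 in KO against Het cells of the draining node, and Id1 at 1.20 over both nodes.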
